A study of Mus musculus with 53 samples.

How the data were processed

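Total RNA of mouse tissues was measured on 53 Affymetrix arrays in 18 groups, given by tissue, age and genotype in the labels. Cornea (7 ages), lung and trachea were on Mouse Gene ST arrays (27 arrays) and bladder, esophagus, stomach, proximal small intestine and dorsal skin on arrays of the older whole-genome 3' type (26 arrays). Per the series text, the cornea, bladder and E18.5 skin arrays came from earlier studies of the same laboratory. The deposited values are intensity values per probe set on a linear scale, summarised by the authors with PLIER 2.0 in Affymetrix Expression Console 1.1.1, per the submitters' processing notes. What normalization between arrays was applied is not given in the sources used here. The deposited intensities ranged from 0 to 78720 in the Gene ST table and from 0 to 134800 in the 3' table. The 2 tables were analysed separately and no test was made across them.

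Intensities were turned into log2(value + 16), so fold changes of dim genes are understated. Array medians of these values ranged from 7.604 to 8.174 in the Gene ST table and from 5.35 to 6.029 in the 3' table. Because these ranges exceeded a limit on array medians set in advance, values were quantile-normalized within each table and the values as deposited served as the alternative. The pseudocount, the normalization rule, the tests, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where an alternative or test is said to have been added later.

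Probe sets were named from the platform annotation, with symbols updated through the RefSeq gene table of assembly GRCm38.p6, which was used for names only. Of 35556 Gene ST probe sets 21789 had 1 gene, 1621 several and 12146 none, and of 45101 probe sets of the 3' type, 34958 had 1 gene, 932 several and 9211 none. Symbols were found in the reference for 99.58% and 99.42% of probe sets with 1 gene. Probe sets with several genes or none were not used. Each gene was represented by its brightest probe set, giving 19938 and 18194 genes. Where a gene had further probe sets, the share of called genes whose second-brightest probe set moved the same way was counted.

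Tests used limma 3.58.1 in R 4.3.3, with lmFit and eBayes over all groups of a table and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05 and at least 2-fold. Cornea ages were tested with the F test over 7 ages and with moderated pairwise contrasts. All tests were two-sided. A gene was enriched in a tissue when called higher than in each other tissue. The change from E14.5 to E16.5 in skin was set against that in bladder by an interaction contrast. In all, 30 gene lists (pathways, cell types of the tissues and other cell types a sample could hold) were tested against all other genes with camera, at a preset correlation between genes of 0.01 and with an estimated correlation as the alternative. In conjunctions that share arrays, unchanged groups were simulated and the overlap of independent lists was computed.

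Genes named in the text followed a fixed rule. Per comparison these were the called genes with an official symbol whose arrays did not overlap between groups, taking the 10 largest increases and 10 largest decreases, or for enriched sets the 12 with the largest smallest margin. By chance 10% of genes do not overlap in 3 against 3 arrays. Per reported list up to 4 called members with the largest change were added, or the member with the largest change where none was called, and Ehf, Grhl3, Klf4, Pax6 and Krt12 could be named in any comparison. At most 2 genes were spelled out per tight gene family of repeated members. Genes of the added marker lists were chosen after the data were seen.

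Replicates were compared before averaging. E14.5 skin replicates 1 and 2 share an identifier in their titles, 1 of them with an added mark that may stand for a rerun. The rule fixed in advance averaged them only if they were the closest pair of a group in their table. The SD of their log2 difference was 0.372, against 0.3088 for the closest such pair, so they entered as 2 samples, and their mean was an alternative. A rerun need not be the closest pair, so this does not show that they are separate samples. Replicate numbers come from the labels. They were taken to pair arrays where every pair of equal numbers had deviations correlated over 0.1, which held only for cornea P28 against P14 (0.133 to 0.242). Alternatives were the values as deposited, a pseudocount of 1, only genes above the table median in a group, the mean of all probe sets, eBayes with trend and robust, only the groups compared, no fold limit, the replicate number as a block, each array left out in turn, and other ages or tissues in a comparison. Other splits of the arrays were drawn up to 100 times, and 40 relabellings for the list tests. The procedure was tested on simulated data with 200 changed genes among the real ones. For cornea P28 against E14.5 (19938 genes), 50% of 2-fold, 92% of 3-fold and 100% of 4-fold changes were called, with 3 unchanged genes. For stomach against esophagus (18194 genes) these shares were 30%, 90% and 96%, with 5 unchanged genes, and for the F test over cornea ages (19938 genes) 80%, 100% and 100%, with 2. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.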

Results

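RNA from mouse epithelial tissues was measured on 53 arrays in 18 groups, to compare the tissues and how cornea, skin and bladder change with age. Whole cornea was sampled at embryonic days E14.5, E15.5 and E17.5 and at postnatal days P3, P7, P14 and P28, with 3 arrays per age. Lung and trachea of E18.5 embryos, 3 arrays each, were measured on the same Gene ST type of array, and these 27 arrays form 1 table of 19938 named genes. The other 26 arrays, of the older whole-genome 3' type with 18194 named genes, hold dorsal skin at E14.5, E16.5 and E18.5, bladder at E14.5, E16.5 and E18.5, and esophagus, stomach and proximal small intestine at E18.5. Each of these groups had 3 arrays, except E14.5 bladder with n = 2. E14.5 skin replicates 1 and 2 share an identifier in their titles and may be 1 sample run again, so its n of 3 arrays may be 2 samples. The E18.5 bladders came from mice heterozygous for Get1 (Grhl3), a grainyhead-like transcription factor needed for the skin barrier, and all other samples came from wild-type CB6 mice. Levels are quantile-normalized log2 intensities given as mean ± SD, with n = 3 arrays per group unless another n is stated. A gene was called higher or lower at a Benjamini-Hochberg adjusted p under 0.05 in limma and a change of at least 2-fold. Fixed gene lists were each tested against all other genes, and beside a list's count of called members the count adjusted over the list alone is given where it differed. Of 540 list tests over 18 comparisons 170 were called with a preset correlation between genes, and 15 of them also with an estimated one. As 17 of 40 relabellings of arrays gave as many, chance was not excluded for this number. With 3 arrays per group, 92% of simulated 3-fold and 50% of 2-fold changes, the limit itself, were called in cornea P28 against E14.5. Whether the arrays of a group came from separate animals or litters is not stated, so all p-values measure only the spread between these arrays, which may be technical. After quantile normalization each rank has the same value on every array, so an SD of 0 beside a bright gene can come from this construction. A level of 4 is the floor that stands for an intensity of 0. Folds of genes near either end depend on the pseudocount and the normalization.

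Cornea samples gained epithelial genes between E14.5 and P28, and of the steps between neighbouring ages E14.5 to E15.5 called the most genes (1507). Krt12, a keratin known from corneal epithelium, rose over a range of 8 log2 units with its lowest mean at E14.5 and its highest at P28 (adjusted p = 1.24e-16). Ehf, an Ets-family transcription factor of epithelial cells, spanned 6.75 log2 units (adjusted p = 7.25e-16), from 5.82 ± 0.14 at E14.5 through 10.9 ± 0.42 at E15.5 to 12.57 ± 0.2 at P28. Klf4, an epithelial factor, spanned 4.7 log2 units (adjusted p = 1.76e-08) and Pax6, an eye regulator, 1.3 (adjusted p = 0.00203) from 11.04 ± 0.65 at E14.5. Grhl3 spanned 1.49 log2 units (adjusted p = 0.0295), with its lowest mean at E17.5 and its highest at P28.

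Across the 7 ages 4321 of 19938 genes changed in limma's F test (adjusted p under 0.05 and at least 2-fold between the lowest and the highest age). Of these, 1657 had their highest mean at P28 and 781 at E14.5, and 1679 had their lowest mean at E14.5 and 1430 at P28. All 14 measured genes of the corneal epithelium list and all 13 of the list of basal stratified epithelium and hemidesmosomes were among them. So were 24 of 28 genes of epithelial junctions, 37 of 41 of the cell cycle, 38 adjusted over the list alone, and 22 of 25 of fibrillar collagens and extracellular matrix, 23 adjusted over the list alone. Further lists with most members changing were corneal stroma and keratan sulfate with 12 of 14, the circadian clock with 13 of 16 and aldehyde and oxidative defence with 17 of 23. Of the cornified envelope and late epidermal differentiation list, 7 of 46 members changed. Markers of other cell types changed as well: 16 of 22 lens genes, 15 of 25 skeletal muscle genes, 17 adjusted over the list alone, 8 of 12 genes of melanocytes and pigment epithelium, 9 of 17 of neurons and Schwann cells and 6 of 11 of erythroid cells.

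**Figure D1:**
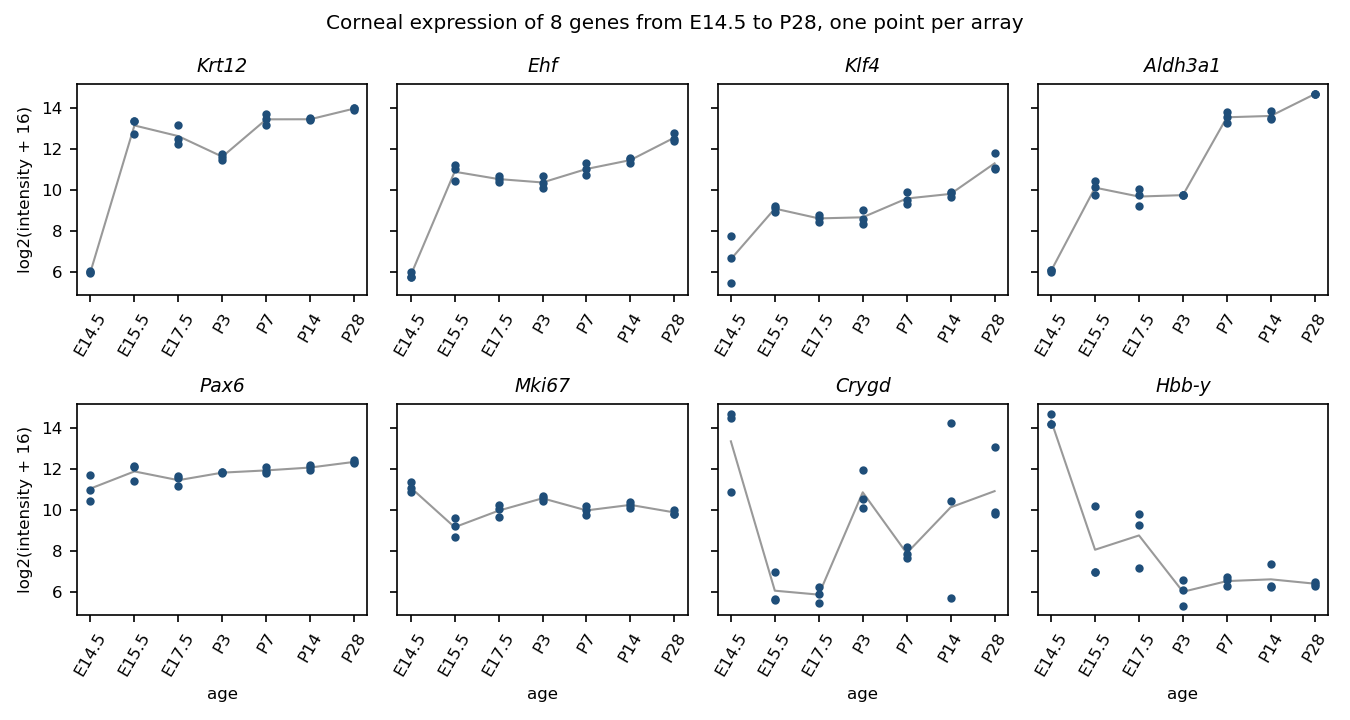
Log2 intensity (y axis) of 8 genes in whole cornea at 7 ages from E14.5 to P28 (x axis), each point an array (n = 3 per age) and each line through the age means. Krt12 and Ehf climb from 5.99 and 5.82 at E14.5 to 13.16 and 10.9 at E15.5, while Hbb-y drops from 14.37 to 8.05.

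Between the youngest and the oldest cornea, P28 against E14.5 (n = 3 each), all 14 of 14 corneal epithelium genes rose (adjusted p = 1.83e-20, adjusted p = 0.00388 with an estimated correlation). Aldh3a1, the aldehyde dehydrogenase that makes up much of the soluble protein of adult corneal epithelium, rose 404-fold (14.7 ± 0 against 6.04 ± 0.05, adjusted p = 5.48e-20). Krt12 rose 257-fold (13.99 ± 0.05 against 5.99 ± 0.06, adjusted p = 1.54e-17). The stratified-epithelial keratins Krt6b (12.96 ± 0.24 against 4.54 ± 0.61), Krt6a (13.02 ± 0.03 against 6.08 ± 0.6) and Krt13 (log2 change 6.98) rose too. Increases were also called for the membrane serine proteases Tmprss11a (7.71) and Tmprss11g (7.69) and the fatty-acid binding protein Fabp6 (7.34). The embryonic globins Hbb-y and Hba-x fell by 7.99 and 6.79, the heart actin Actc1 by 5.23, the matrix proteoglycan Vcan by 5.06, and the neurofilament Nefm by 4.75. The lens crystallin Cryga fell by 4.93, with arrays far apart at both ages (8.51 ± 1.58 against 13.44 ± 2). The lipid receptor S1pr3 (-5.72) and the transcription factor Sox11 (-5.07) also fell.

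Other called corneal epithelium genes were Ehf (12.57 ± 0.2 against 5.82 ± 0.14), the uroplakin Upk1b (5.54) and Klf4 (4.7). Of basal stratified epithelium, 12 of 13 rose (adjusted p = 3.79e-08, adjusted p = 0.108 with an estimated correlation). Krt15 was at 12.57 ± 0.31 against 9.45 ± 0.36 and the laminin subunit Lama3 was up by 3.54. Of epithelial junctions, 20 of 28 rose (adjusted p = 6.59e-12, adjusted p = 0.108 with an estimated correlation). They were led by the desmosomal cadherins Dsc3 (12.48 ± 0.15 against 6.98 ± 1.35) and Dsg3 (5.05) and the tight-junction claudin Cldn7 (4.4). Of nonkeratinised stratified epithelium, 8 of 14 rose (adjusted p = 2.52e-06, adjusted p = 0.0222 with an estimated correlation). Epithelial transcription factors rose in 14 of 33 and fell in 1 (adjusted p = 6.23e-05, adjusted p = 0.108 with an estimated correlation). The rises included Hopx (4.84) and Elf3 (3.37). Circadian clock genes rose in 10 of 16 cases and fell in 1 (adjusted p = 1.52e-07, adjusted p = 0.0162 with an estimated correlation). Hlf was at 12.29 ± 0.26 against 7.63 ± 0.72, Bhlhe40 rose by 3.71 and the heme receptor Nr1d1 by 3.7. Aldehyde and oxidative defence genes rose in 8 of 23 and fell in 2 (adjusted p = 0.00793, adjusted p = 0.108 with an estimated correlation). The rises included the glutathione transferases Gsto1 (13.43 ± 0.15 against 8.31 ± 0.1) and Gsta3 (5.05) and the quinone reductase Nqo1 (3.01). The interferon and antigen presentation list rose in 10 of 21 (adjusted p = 6.78e-07, adjusted p = 0.147 with an estimated correlation), for example the immunoproteasome subunit Psmb8 (10.66 ± 0.71 against 6.51 ± 0.12).

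Cell cycle genes fell in 29 of 41 (adjusted p = 3.58e-13, adjusted p = 0.173 with an estimated correlation). Examples were the spindle checkpoint kinase Bub1 (8.69 ± 0.16 against 10.5 ± 0.38) and the survivin gene Birc5 (-1.5). Markers of other cell types moved in the same comparison. Erythroid genes fell in 6 of 11 (adjusted p = 1.5e-05, adjusted p = 0.0481 with an estimated correlation). Lens genes fell in 11 of 22 and rose in 1 (adjusted p = 0.0161, adjusted p = 0.649 with an estimated correlation). Genes of neurons and Schwann cells fell in 7 of 17 (adjusted p = 0.00801, adjusted p = 0.406 with an estimated correlation), and of skeletal muscle in 5 of 25, 4 adjusted over the list alone, (adjusted p = 0.0352, adjusted p = 0.649 with an estimated correlation). The corneal stroma list had 6 of 14 members rising (adjusted p = 0.0352, adjusted p = 0.507 with an estimated correlation). Examples were Kera, a keratan sulfate proteoglycan (12.15 ± 0.22 against 8.3 ± 2), and Angptl7 (4.47). In all, 2780 genes were called, 1675 higher and 1105 lower at P28. The balance turned without a fold limit (3797 and 4767) and from E15.5 (976 and 1076). Of called genes with a second probe set, 95.2% moved the same way on it.

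Within a day, from E14.5 to E15.5 (n = 3 each), the cell cycle list fell in 38 of 41 members (adjusted p = 1.04e-38, adjusted p = 0.0237 with an estimated correlation). Krt12 rose 145-fold (13.16 ± 0.36 against 5.99 ± 0.06, adjusted p = 2.99e-16) and Ehf 33.8-fold (10.9 ± 0.42 against 5.82 ± 0.14, adjusted p = 9.86e-15). The protease inhibitors A2m (6), Serpinb11 (5.61) and Serpinb5 (4.99), the keratins Krt13 (5.46) and Krt6a (5.32), the carbonyl reductase Cbr2 (5) and the matrix thrombospondin Thbs4 (11.93 ± 0.37 against 6.34 ± 0.73) rose as well. The lens crystallins Cryga (5.82 ± 2.35 against 13.44 ± 2), Crygd (-7.32), Cryba4 (-5.27), Cryba1 (-5) and Crybb1 (-4.33) and the embryonic globins Hbb-y (8.05 ± 1.87 against 14.37 ± 0.28) and Hba-x (-6.48) fell.

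Of cell cycle genes, Bub1 was at 8.1 ± 0.59 against 10.5 ± 0.38 and the nucleotide reductase subunit Rrm2 fell by 2.38. Fibrillar collagens and matrix rose in 20 of 25 (adjusted p = 2.09e-15, adjusted p = 0.09 with an estimated correlation). Col6a1 was at 12.19 ± 0.21 against 7.29 ± 1.43 and Col1a1 at 12.62 ± 0.16 against 8.75 ± 0.96. Corneal epithelium rose in 9 of 14 (adjusted p = 7.12e-15, adjusted p = 0.022 with an estimated correlation), Aldh3a1 by 4.08 and Upk1b by 3.94. Corneal stroma rose in 8 of 14 (adjusted p = 5.14e-05, adjusted p = 0.101 with an estimated correlation). Kera (12.96 ± 0.11 against 8.3 ± 2) and Lum (2.83) led it, while Aldh1a1, a retinaldehyde dehydrogenase of the same list, fell by 3.12. Basal stratified epithelium rose in 9 of 13 (adjusted p = 4.81e-08, adjusted p = 0.101 with an estimated correlation), Krt15 by 3.81. Epithelial junctions rose in 16 of 28 (adjusted p = 6.73e-09, adjusted p = 0.189 with an estimated correlation), Dsg3 by 3.98. Nonkeratinised stratified epithelium rose in 6 of 14 (adjusted p = 0.000141, adjusted p = 0.0569 with an estimated correlation), the membrane protein Mal by 4.52. Circadian clock genes rose in 5 of 16 (adjusted p = 1.3e-05, adjusted p = 0.0342 with an estimated correlation), Hlf by 3.46. Epithelial transcription factors rose in 9 of 33 (adjusted p = 0.000979, adjusted p = 0.189 with an estimated correlation), among them Zfp750 (2.62), Klf5 (2.54) and Klf4 (2.48). Grhl3 differed by 0.51 (adjusted p = 0.37) and Pax6 by 0.84 (adjusted p = 0.0117), below the 2-fold limit.

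Lens genes fell in 15 of 22, 16 adjusted over the list alone, (adjusted p = 6.32e-09, adjusted p = 0.235 with an estimated correlation). Erythroid genes fell in 4 of 11 (adjusted p = 3.63e-07, adjusted p = 0.0237 with an estimated correlation). Genes of neurons and Schwann cells fell in 7 of 17 (adjusted p = 0.0293, adjusted p = 0.477 with an estimated correlation). Cell cycle and matrix shifts may partly reflect such other cells. The comparison called 1507 genes, 1057 higher and 450 lower at E15.5, or 2994 and 2277 without a fold limit.

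From E15.5 to E17.5 (n = 3 each) few genes changed, and those that rose included genes of contractile and pigmented cells. The pericyte regulator Rgs5 rose from 6.19 ± 1.19 to 9.19 ± 1.21 (adjusted p = 0.0333), smooth muscle actin Acta2 from 8.29 ± 1.17 to 10.61 ± 0.58, and the melanin enzyme Tyrp1 from 7.96 ± 1.06 to 9.99 ± 0.49. The creatine kinase Ckb (2.29), the muscle growth inhibitor Mstn (2.12) and the calcium pump Atp2a1 (1.68) rose too. The epithelial adhesion molecule Epcam fell from 10.63 ± 0.13 to 9.19 ± 0.4 and the calpain subunit Capns2 from 9.84 ± 0.46 to 8.23 ± 0.64, and Csta1 (-1.37) and Bcl6 (-1.02) fell. Krt12 (-0.53, adjusted p = 0.348) and Ehf (-0.36, adjusted p = 0.495) were not called.

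The cell cycle list shifted up, with 6 of 41, 7 adjusted over the list alone, members called (adjusted p = 7.91e-39, adjusted p = 0.0703 with an estimated correlation). Among them were Cdk1 (9.99 ± 0.21 against 8.82 ± 0.61) and Rrm2 (1.17). Skeletal muscle shifted up with 3 of 25, 16 adjusted over the list alone, called (adjusted p = 9.72e-14, adjusted p = 0.144 with an estimated correlation), and its signal sat in single arrays, with Myh3 at 10.32, 7.14 and 7.88 at E15.5 and 12.15, 7.81 and 11.87 at E17.5. The Myh3 change of 2.17 ranged from 1.4 without E17.5 replicate 1 to 3.57 without replicate 2. Melanocyte and pigment epithelium did so with 1 of 12, 6 adjusted over the list alone, called (adjusted p = 4.02e-10, adjusted p = 0.144 with an estimated correlation). Epithelial junctions shifted down with 1 of 28 called (adjusted p = 2.98e-10, adjusted p = 0.21 with an estimated correlation). Basal stratified epithelium also shifted down, with 0 of 13 called (adjusted p = 0.00123, adjusted p = 0.447 with an estimated correlation). The comparison called 61 genes, 52 higher and 9 lower, and as deposited, without normalization between arrays, 30 higher and 13 lower. Leaving out any of the 6 arrays moved this count by over 1.5 times, to between 3 and 298. With only these 2 ages in the fit limma called 0 genes, against 228 at an unadjusted p under 0.05 and 2-fold.

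Around birth, at P3 against E17.5 (n = 3 each), skeletal muscle genes fell in 14 of 25, 15 adjusted over the list alone, in the cornea samples (adjusted p = 4.88e-11, adjusted p = 0.707 with an estimated correlation). The muscle genes Actc1 (6.8 ± 0.03 against 12.17 ± 1.7), Mylpf (-4.66), Tnnc1 (-3.98), Myl4 (-3.76) and Myh3 (6.95 ± 0.25 against 10.61 ± 2.43) fell. The muscle signal sat in E17.5 replicates 1 and 3, with Acta1 at 12.41, 9.21 and 12.55 on the 3 E17.5 arrays and at 7.52, 7.89 and 8.49 at P3. The lens crystallins Crygd (10.86 ± 0.96 against 5.85 ± 0.38) and Crygc (3.56), the photoreceptor genes Pdc (3.43) and Gngt1 (3.33), the neurogenic factor Neurod4 (2.86), Krt6b (10.96 ± 0.11 against 8.1 ± 0.16) and the retinol-binding protein Rbp2 (2.34) rose. Xist, the RNA that coats the inactive X chromosome, was at 12.54 ± 0.16 against 6.96 ± 1.44, and the Y-linked Kdm5d and Uty fell by 4.68 and 3.72, genes known to follow the sex of the animals, which the labels do not give. Krt12 was lower at P3 (11.63 ± 0.14 against 12.64 ± 0.47, adjusted p = 0.00655).

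Lens genes rose in 2 of 22, 5 adjusted over the list alone, (adjusted p = 0.000264, adjusted p = 0.782 with an estimated correlation). The gastric epithelium list rose in 2 of 21 (adjusted p = 0.04, adjusted p = 0.778 with an estimated correlation). Its called members were Gast, the hormone gastrin (1.36), and Muc1, a mucin of many epithelial surfaces (1.25). The comparison called 285 genes, 90 higher and 195 lower, or 129 higher and 151 lower as deposited. With only these 2 ages in the fit 136 genes were called.

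From P3 to P7 (n = 3 each) genes of melanocyte and pigment epithelium fell in 7 of 12 (adjusted p = 8.37e-09, adjusted p = 0.16 with an estimated correlation). Aldh3a1 rose 14.1-fold (13.56 ± 0.26 against 9.75 ± 0.01, adjusted p = 2.9e-12) and Krt12 from 11.63 ± 0.14 to 13.46 ± 0.27 (adjusted p = 2.5e-05). The proteases Tmprss11d (11.14 ± 0.72 against 6.32 ± 0.65), Tmprss11a (3.24) and Tmprss11e (3.14), Adh7 (12.29 ± 0.28 against 9.9 ± 0.43), Angptl7 (2.36) and the aldo-keto reductase Akr1c13 (2.28) rose. Neurod4 (6.72 ± 0.56 against 11.57 ± 0.95), the retinal factors Otx2 (-4.15) and Rorb (-3.79), Neurod1 (-3.61), and the glial lipid-binding protein Fabp7 (-3.8) fell. So did Nefl (-3.61), the synaptic Snap25 (-3.43), the neuronal tubulin Tubb3 (-2.89), the melanin enzyme Dct (7.28 ± 1.08 against 10.95 ± 0.27) and the endothelial sialomucin Emcn (-3.02). Ehf was 0.66 higher (adjusted p = 0.0322), short of 2-fold.

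Aldehyde and oxidative defence genes rose in 4 of 23 (adjusted p = 5.69e-05, adjusted p = 0.0588 with an estimated correlation), including Gsta3 (2.02), Aldh1a7 (1.83) and Nqo1 (1.39). Corneal epithelium rose in 3 of 14 (adjusted p = 5.39e-06, adjusted p = 0.16 with an estimated correlation), including the transketolase Tkt (1.39). The circadian clock rose in 4 of 16 and fell in 1 (adjusted p = 0.00424, adjusted p = 0.176 with an estimated correlation). The rises included Per3 (1.42) and Dbp (1.08), and the decrease was Nfil3 (-1.73). Neurons and Schwann cells fell in 4 of 17, 6 adjusted over the list alone, (adjusted p = 7.03e-05, adjusted p = 0.176 with an estimated correlation). The comparison called 284 genes, 173 higher and 111 lower at P7.

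Between P7 and P14 (n = 3 each) 3 genes passed. Cmah, a hydroxylase of sialic acid (9.62 ± 0.18 against 7.6 ± 0.58, adjusted p = 0.044), and Sectm1b (8.99 ± 0.46 against 7.44 ± 0.03, adjusted p = 0.000118) were higher at P14. The vessel growth factor Angpt2 was lower (8.53 ± 0.4 against 9.72 ± 0.16, adjusted p = 0.044). In the list tests 8 lists shifted with no called member. Corneal epithelium (adjusted p = 1.57e-05, adjusted p = 0.367 with an estimated correlation) and epithelial transcription factors (adjusted p = 1.85e-05, adjusted p = 0.367 with an estimated correlation) shifted up. So did lens (adjusted p = 1.07e-06, adjusted p = 0.588 with an estimated correlation), with Crygd at 5.7, 14.25 and 10.42 on the 3 P14 arrays. Collagens and matrix shifted down (adjusted p = 0.000555, adjusted p = 0.588 with an estimated correlation). At an unadjusted p under 0.05 and 2-fold, limma gave 74 genes. The count was 1 as deposited, 1 with a pseudocount of 1, 0 with only these 2 ages in the fit, and between 1 and 18 with an array left out.

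From P14 to P28 (n = 3 each) collagens and matrix fell in 20 of 25 (adjusted p = 4.17e-18, adjusted p = 0.18 with an estimated correlation), Fbn2 (-2.78) and Postn (-2.73) among them. Cyp2b19, an epidermal cytochrome P450, rose 53.9-fold (13.82 ± 0.29 against 8.07 ± 0.44, adjusted p = 1.25e-15). The secreted Slurp1 (12.38 ± 0.05 against 9.01 ± 0.22), the surface antigens Psca (3.67) and Ly6g6c (3.26), the cytokine Il1f9 (3.64), Plekhs1 (3.4), Samd12 (3.24), Trim12a (3.41), Apol7a (3.23) and the long RNA Lncpint (3.49) rose. Col14a1 (7.21 ± 0.7 against 11.06 ± 0.39), Vwde (6.73 ± 0.22 against 11.39 ± 0.8), Otor (-4.48) and the tachykinin Tac1 (-4.11) fell. So did Krtdap (-3.94), Ecrg4 (-3.84), Gabrp (-3.72), the amino acid carrier Slc38a4 (-3.26), S1pr3 (-3.2) and Cthrc1 (-3.13). Ehf rose from 11.46 ± 0.13 to 12.57 ± 0.2 (adjusted p = 0.000241).

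Corneal stroma fell in 5 of 14, 6 adjusted over the list alone, with 1 rising (adjusted p = 0.00346, adjusted p = 0.386 with an estimated correlation). Examples were Col8a1 (-2.52), Fmod (-2.3) and Chst5 (-2.17). Simple epithelial keratins fell in 4 of 6 with 1 rising (adjusted p = 0.017, adjusted p = 0.528 with an estimated correlation), including Krt7 (-2.48) and Krt19 (-2.26). Corneal epithelium rose in 5 of 14 with 1 falling (adjusted p = 4.26e-07, adjusted p = 0.18 with an estimated correlation). The water channel Aqp5 was at 12.28 ± 0.04 against 9.12 ± 0.2, Klf4 rose by 1.5 and the limbal marker Gpha2 fell (-1.3). Epithelial junctions rose in 3 of 28 with 1 falling (adjusted p = 0.00168, adjusted p = 0.528 with an estimated correlation). The circadian clock rose in 2 of 16 (adjusted p = 0.00351, adjusted p = 0.275 with an estimated correlation), by Nr1d1 (1.61) and Arntl (1.05). The replicate number paired the arrays here, and with it as a block 2 further lists were called, nonkeratinised stratified epithelium (adjusted p = 0.0613 without and 0.00795 with it) and epithelial transcription factors (0.0999 and 0.0175). Both calls were lost (adjusted p = 0.545 and adjusted p = 0.459 with an estimated correlation and the block). The comparison called 891 genes, 324 higher and 567 lower at P28, or 539 and 532 as deposited and 1416 and 1315 without a fold limit.

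**Figure D2:**
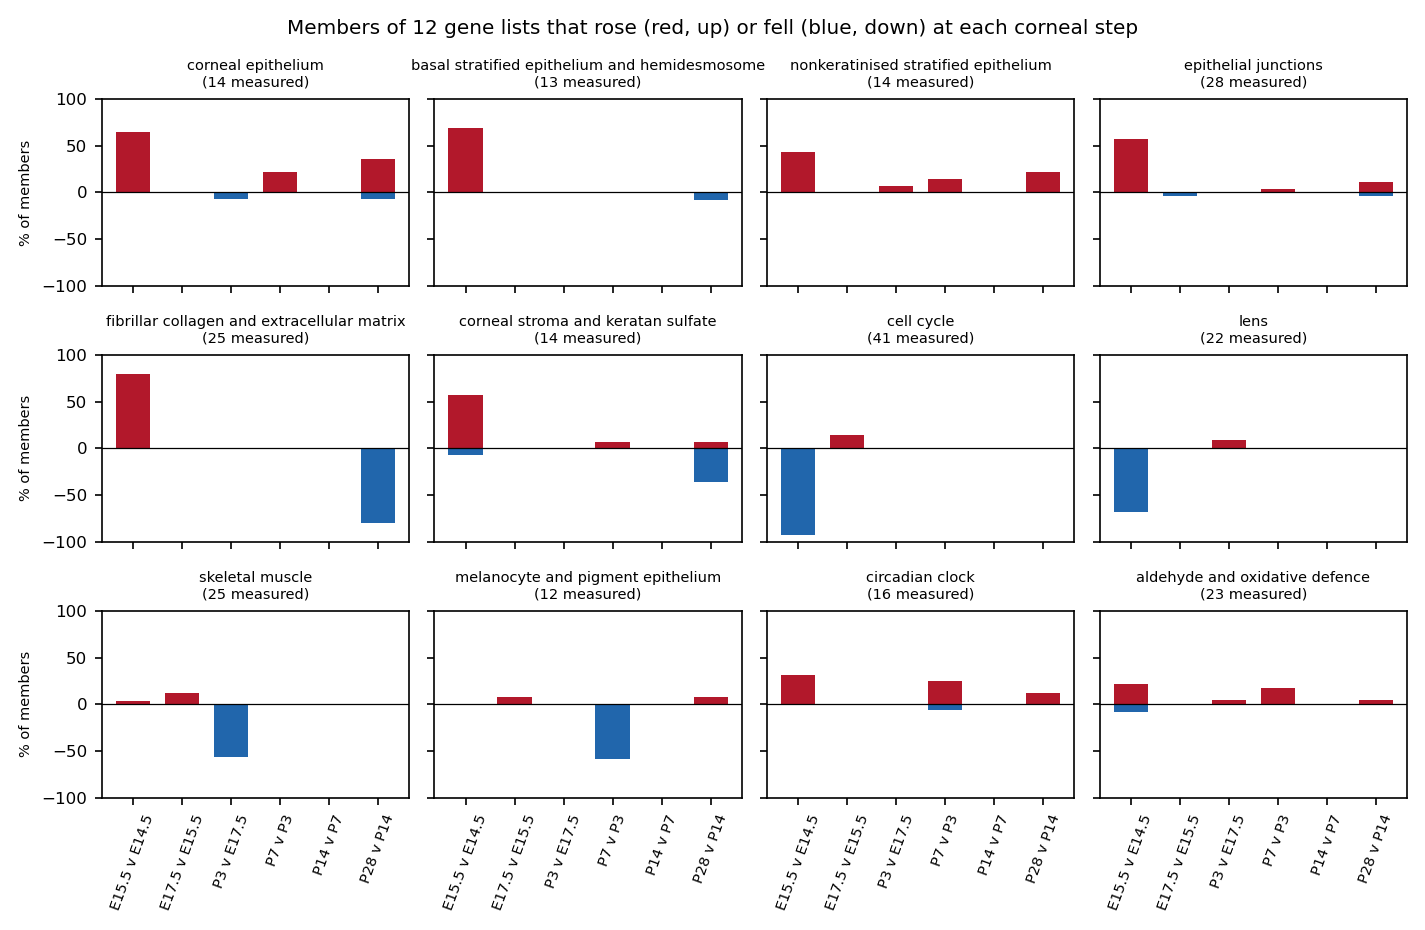
Percent of measured members of 12 gene lists (y axis) called higher (red bars, up) or lower (blue bars, down) at each of 6 steps between neighbouring cornea ages (x axis). The step from E14.5 to E15.5 moves 38 of 41 cell cycle genes down and 20 of 25 matrix genes up, and the step from P14 to P28 moves 20 of 25 matrix genes down.

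Cornea at E17.5 was set against lung and trachea at E18.5 (n = 3 each), the other tissues of its table. The 3 arrays labelled lung carried thymus-type transcripts, and 1 of 15 lung alveolar genes was called higher in them than in trachea, so they are called the arrays labelled lung throughout. Higher in cornea than in both were Krt12 (12.64 ± 0.47 against 6.12 ± 0.27 in the arrays labelled lung and 5.86 ± 0.45 in trachea, at least 91.6-fold) and Pax6 (11.45 ± 0.26 against 5.06 ± 0.28 and 5.51 ± 0.32). So were Tfap2b (smaller log2 margin 5.55), Gpr39 (5.42), Otx2 (5.37), the pigment genes Dct (5.17) and Slc24a5 (5.04), A2m (5.08) and Mgarp (4.87). Otx2 and Dct fell in cornea from P3 to P7 (-4.15 and -3.68) and may not mark cornea itself. Lower than in both were the lectin Reg3g (margin -5.19), Pgm5 (-3.86) and Btg1 (-3.74). The Y-linked Kdm5d (5.09) and Eif2s3y (5.03) were also higher and Xist lower (6.96 ± 1.44 against 13.25 and 13.09), but these genes are known to follow sex, and Kdm5d was at 5.6, 5.03 and 5.67 in P3 cornea. Ehf did not differ detectably from trachea (10.54 ± 0.16 against 10.77 ± 0.17, adjusted p = 0.293), nor did Klf4 (-0.18, adjusted p = 0.679).

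Genes higher in cornea than in both numbered 1164, against 211 for independent lists of equal lengths, and lower ones 836, against 206. Part of this excess may come from the shared cornea arrays. Groups simulated as unchanged gave 0. Among the genes higher than in both were 7 of 12 of melanocyte and pigment epithelium, 6 of 14 of corneal stroma and 6 of 17 of neurons and Schwann cells. They also held 5 of 14 of corneal epithelium, 5 of 28 of epithelial junctions and 4 of 13 of basal stratified epithelium. The lower ones held 8 of 41 of the cell cycle. Against trachea alone, cartilage genes were lower in cornea in 16 of 19 (adjusted p = 1.55e-15, adjusted p = 0.00714 with an estimated correlation), for example the link protein Hapln1 (6.98 ± 0.27 against 13.18 ± 0.02). Genes of airway ciliated and secretory cells were lower in 9 of 22 (adjusted p = 4.94e-09, adjusted p = 0.000277 with an estimated correlation), for example the secretoglobin Scgb3a2 (-6.48). Between cornea and these tissues a lower share of second probe sets moved with the called gene, 81.4% against the arrays labelled lung and 78.6% against trachea, than between cornea ages. The cornea arrays came from an earlier study, so tissue and array run cannot be told apart here. The median of all genes stood 0.11 and 0.09 higher in cornea, and 0.38 and 0.34 higher as deposited.

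Trachea against the arrays labelled lung at E18.5 (n = 3 each) had cartilage genes higher in trachea in 18 of 19 (adjusted p = 9.27e-23, adjusted p = 0.000991 with an estimated correlation). Higher in trachea were the cartilage genes Col11a1 (202-fold, 13.17 ± 0.02 against 5.51 ± 0.67) and Hapln1 (6.83), and the muscle genes Myh3 (6.61), Myh8 (6.24) and Mybpc1 (6.14). So were the club cell cytochrome Cyp2f2 (14.21 ± 0.08 against 7.95 ± 0.02), Aldh1a7 (6.25), the signal Wnt5a (6.39), and thyroglobulin, Tg (13.89 ± 0.33 against 7.37 ± 0.13), the hormone precursor of thyroid. Higher in the arrays labelled lung were the T-cell development gene Themis (6.16 ± 0.31 against 13.67 ± 0), the recombinase Rag1 (6.78 ± 0.04 against 14.22 ± 0.06), the co-receptor Cd8a (7.35 ± 0.05 against 14.04 ± 0.07), and Cd3g (-6.54). Further such genes were Ptprc (-6.56), the granzyme Gzma (-6.88) and the milk casein Csn2 (-6.8).

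Airway ciliated and secretory genes were higher in trachea in 12 of 22 and lower in 1 (adjusted p = 4.6e-10, adjusted p = 0.000179 with an estimated correlation), including Scgb3a2 (6.1), Scgb3a1 (4.91) and the mucin Muc5b (3.98). Skeletal muscle genes were higher in 22 of 25 (adjusted p = 4.13e-15, adjusted p = 0.0798 with an estimated correlation). Collagens and matrix were higher in 23 of 25 (adjusted p = 2.3e-11, adjusted p = 0.124 with an estimated correlation). Cell cycle genes were lower in trachea in 37 of 41 (adjusted p = 3.37e-17, adjusted p = 0.12 with an estimated correlation). Immune cell genes were lower in 11 of 26 (adjusted p = 1.1e-08, adjusted p = 0.0798 with an estimated correlation), such as Cd74 (-5.76) and H2-Aa (-6.05). Interferon and antigen presentation genes were lower in 15 of 21 (adjusted p = 1.61e-09, adjusted p = 0.0939 with an estimated correlation), such as Psmb8 (-3.72). Of 15 lung alveolar genes, 1 was higher and 2 were lower in the arrays labelled lung than in trachea, Rtkn2 by 1.23 and Hopx and Etv5 by -2.5 and -1.34. Of the 15, 4 varied at least 2-fold over cornea ages with 0 called higher, too few to judge. Ehf (3.71), Klf4 (2.01) and Grhl3 (1.77) were higher in trachea. The comparison called 3212 genes, 2163 higher and 1049 lower in trachea, or 4384 and 4163 without a fold limit.

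**Figure D3:**
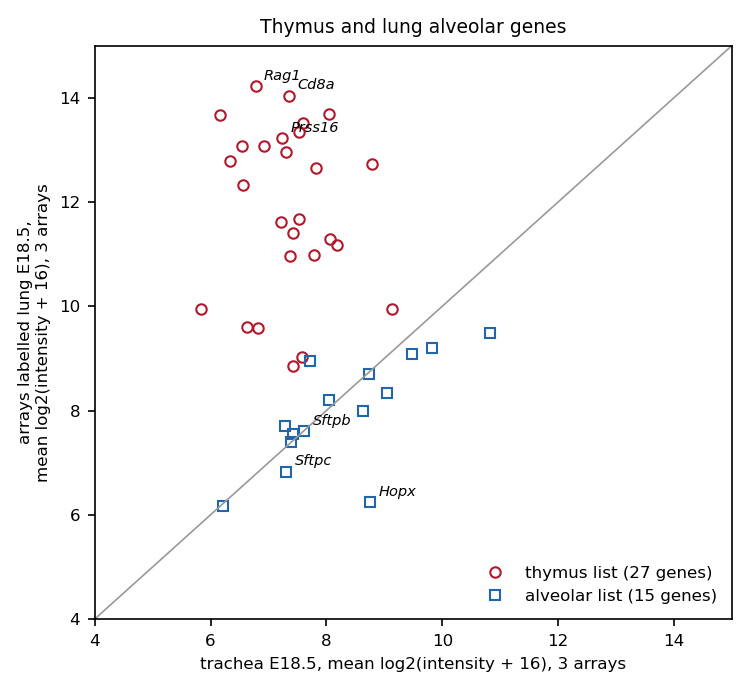
Mean log2 intensity in the arrays labelled lung (y axis, n = 3) against trachea (x axis, n = 3) for 27 thymus genes (red circles) and 15 lung alveolar genes (blue squares), with the line of equal values. Of the thymus genes, 26 were called higher in the arrays labelled lung, and of the alveolar genes 1 was called higher and 2 lower.

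The second table, of skin, bladder and the digestive organs, fell into 2 sets of arrays that did not follow the organs. The small intestine and the E16.5 and E18.5 skin arrays stood apart from all others, E14.5 skin included. E14.5 skin correlated with bladder, esophagus and stomach at a mean of 0.911 over genes, but with E16.5 skin at 0.747. For 4201 genes with 2 probe sets, the log2 ratios of the pair correlated at 0.236 to 0.389 across this divide and at 0.451 to 0.849 within the larger side. On the other side they correlated at 0.776 and 0.724 for small intestine with skin, but at 0.265 for E16.5 with E18.5 skin, as low as across. The unshared SD of the 2 ratios was 1.41 to 1.6 across and 0.226 to 0.563 within. These are correlations over genes, which are not independent replicates. The labels record no batch. Comparisons across the divide are therefore given with the share of called genes whose second probe set moved the same way, and tissue or age and the divide cannot be told apart in them.

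**Figure D4:**
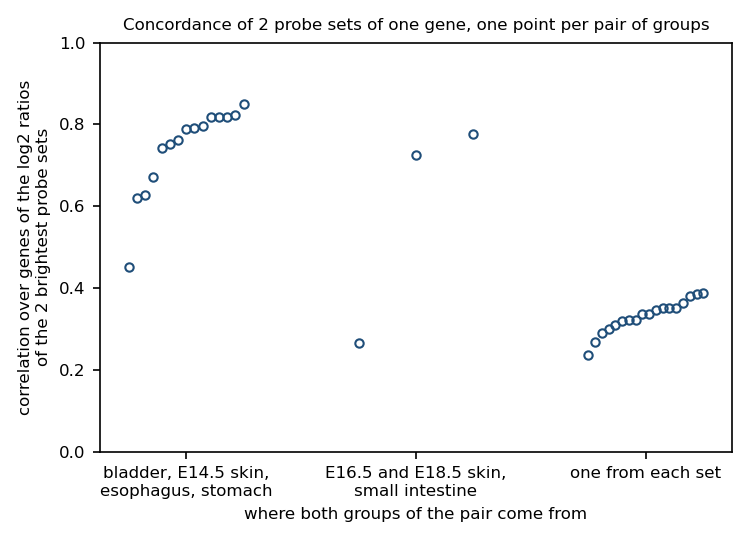
Correlation over 4201 genes of the log2 ratios given by the 2 brightest probe sets of a gene (y axis), each point a pair of groups, for pairs within either side of the divide and pairs across it (x axis). Pairs across the divide lie between 0.236 and 0.389, and pairs within the sides between 0.451 and 0.849 and between 0.265 and 0.776.

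In skin from E14.5 to E16.5 (n = 3 each) cornified envelope genes rose in 29 of 45 (adjusted p = 1.06e-06, adjusted p = 0.94 with an estimated correlation). Serpina12, the adipokine vaspin, was 576-fold higher (13.85 ± 0.49 against 4.68 ± 0.44, adjusted p = 8.52e-18). The desmosomal cadherin Dsc1 was at 14.89 ± 0 against 6.89 ± 0.08, the desquamation protease Klk7 at 11.39 ± 0.46 against 4.01 ± 0.02, and the late cornified envelope genes Lce1b and Lce1m rose by 7.17 and 7.07. The nucleolar Nol6 (7.85) and Hoxa7 (6.97) rose. Grhl3 rose from 8.49 ± 0.22 to 11.23 ± 0.23 (adjusted p = 0.0102) and Klf4 by 1.37, while Ehf differed by 0.12 (adjusted p = 0.777). Krt12 rose too (9.76 ± 0.47 against 4.34 ± 0.13, adjusted p = 1.79e-13). Map3k12 (-7.08) and Thoc1 (-6.75) fell. The liver-type genes Afp (4.32 ± 0.36 against 11.04 ± 3.93), Apoa1 (4.3 ± 0.17 against 10.5 ± 4.43), Ttr (-5.97) and Apom (-5.63) also fell. At E14.5, Afp was at 13.39 and 13.24 in replicates 1 and 2 and at 6.5 in replicate 3.

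Skeletal muscle genes rose in 18 of 25 (adjusted p = 1.06e-06, adjusted p = 0.94 with an estimated correlation), for example Ckm (5.88) and Myh8 (5.08). Vascular endothelium rose in 9 of 16 with 3 falling (adjusted p = 0.0179, adjusted p = 0.94 with an estimated correlation), for example Sox18 (4.36) and Eng (2.8). The comparison called 7856 genes, 3310 higher and 4546 lower, or 3138 higher and 2799 lower with the mean of all probe sets of a gene. With E14.5 replicates 1 and 2 averaged it called 7722. It lay across the divide, and 60.6% of second probe sets moved with the called gene, 39.3% by 2-fold, weak support.

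From E16.5 to E18.5 (n = 3 each), ages on the same side of the divide, skin gained hair follicle and placode genes in 15 of 27 (adjusted p = 9.97e-13, adjusted p = 0.0331 with an estimated correlation). E18.5 skin came from an earlier study, so age and study cannot be told apart. The inner root sheath keratins Krt27 (12.18 ± 1.3 against 4.03 ± 0.05), Krt25 (6.66), Krt71 (6.45) and Krt73 (4.93) and the hair keratin Krt35 (6.69, or 5.28 without E16.5 replicate 3) rose. Further increases were the fat-cell hormone Adipoq (12.36 ± 0.84 against 5.58 ± 2.27), the glycerol enzyme Gpd1 (6.96) and Csn2 (6.32, at 7.35, 10.62 and 13.31 at E18.5, or 4.88 without replicate 3 and 7.86 without replicate 1). Krtap13 (4.12 ± 0.12 against 11.12 ± 0.94), Saa1 (-6.52), Krt77 (-5.77), Capn12 (-5.74, or -8.43 without E16.5 replicate 1) and Lce3f (-5) fell. Ehf fell from 5.99 ± 0.18 to 4.81 ± 0.22 (adjusted p = 0.0259), and Grhl3 was lower by -2.43 without passing (adjusted p = 0.0788).

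Melanocyte genes rose in 4 of 11, 5 adjusted over the list alone, (adjusted p = 0.00413, adjusted p = 0.254 with an estimated correlation), Dct by 1.93 and Tyrp1 by 4.75, or 2.4 without E16.5 replicate 1. On the E16.5 arrays Tyrp1 was at 4.05, 10.9 and 11.34 and Capn12 at 5.34, 13.53 and 13.29. Erythroid genes fell in 4 of 14 (adjusted p = 0.0177, adjusted p = 0.132 with an estimated correlation). The airway secretoglobins Scgb3a2 (1.8) and Scgb1a1 (1.57) were called higher. The surfactant gene Sftpc was at 4.07, 13.73 and 13.21 on E18.5 replicates 1, 2 and 3 (adjusted p = 0.0647) and at 4, 7.15 and 6.82 at E16.5. The comparison called 808 genes, 444 higher and 364 lower at E18.5, or 334 higher and 662 lower as deposited, and 507 genes with the mean of all probe sets. Second probe sets moved with the called gene in 69.9% and by 2-fold the same way in 20.8%, less than from E14.5 to E16.5.

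Over the whole span, skin at E18.5 against E14.5 (n = 3 each) was higher in Serpina12 (878-fold), the filaggrin gene Flg (12.36 ± 0.16 against 4.62 ± 0.38), the late envelope genes Lce1c (12.05 ± 0.34 against 4.09 ± 0.16) and Lce1a1 (7.64), Tyrp1 (8.52), Krt35 (8.4), Krt27 (7.9) and Adipoq (7.68). The embryonic globin Hbb-y (4.88 ± 0.57 against 12.13 ± 0.38), Krt4, a keratin of moist stratified epithelium (-5.93), the ribosomal gene Rpl27a (-6.63), Thoc1 (-7.32) and the liver proteins Afp (-6.8) and Apoa1 (-6.2) fell. Ehf was lower (-1.06, adjusted p = 0.0104), but 0.07 higher with the mean of all its probe sets, and Krt12 was higher (9.68 ± 0.71 against 4.34 ± 0.13). Cornified envelope genes rose in 26 of 45, 27 adjusted over the list alone, and fell in 3 (adjusted p = 6.54e-05, adjusted p = 0.911 with an estimated correlation). Hair follicle genes rose in 17 of 27 and fell in 4 (adjusted p = 0.00384, adjusted p = 0.842 with an estimated correlation), the rises including Lhx2 (5.38). Skeletal muscle rose in 20 of 25 and fell in 2 (adjusted p = 5.21e-07, adjusted p = 0.842 with an estimated correlation). Collagens and matrix rose in 14 of 25 and fell in 1 (adjusted p = 0.00388, adjusted p = 0.911 with an estimated correlation), including the elastin gene Eln (3.67). The comparison called 7761 genes, 3392 higher and 4369 lower, across the divide, and only 63.5% of second probe sets moved with the called gene. The median of all genes fell by 0.15, and by 0.22 as deposited.

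In bladder the Get1 gene itself, Grhl3, was at 6.53 ± 0.07 (n = 2) at E14.5, 7.03 ± 0.31 at E16.5 and 7.49 ± 0.19 in the heterozygous E18.5 samples, and none of these steps was called. The fit pooled the spread of all groups, and Grhl3 had an SD of 3.36 in small intestine. A missing call for Grhl3 therefore says little about bladder. From E14.5 (n = 2) to E16.5 (n = 3) the called increases included muscle and uroplakin genes. The intermediate filament gene Synm rose from 5.9 ± 0.5 to 8.45 ± 0.55, and skeletal actin Acta1 from 7.62 ± 0.44 to 10.05 ± 0.37. Tnnt3 (2.35), Art3 (2.69), Ank1 (2.18), Actc1 (1.95), Pvalb (1.89) and the interferon-induced Gbp2b (3.64, adjusted p = 0.0497) rose. Sall4, a factor of pluripotent and germ cells, fell from 8.63 ± 1.14 to 6.77 ± 0.18, with the germ-line genes Tdrd12 (-1.05) and Obox3 (-1.47). Urothelium rose in 2 of 16, 3 adjusted over the list alone, (adjusted p = 4.05e-05, adjusted p = 0.19 with an estimated correlation), by the uroplakins Upk3a (7.8 ± 0.16 against 6.22 ± 0.28) and Upk1a (1.34). Smooth muscle rose in 2 of 15, 3 adjusted over the list alone, (adjusted p = 8e-10, adjusted p = 0.19 with an estimated correlation), including desmin, Des (1.44). Skeletal muscle rose in 4 of 25, 5 adjusted over the list alone, (adjusted p = 1.79e-08, adjusted p = 0.19 with an estimated correlation). The comparison called 62 genes, 49 higher and 13 lower. Without E14.5 replicate 1 it called 100 and without E16.5 replicate 3 it called 33. With only these groups in the fit limma called 0, against 244 at an unadjusted p under 0.05 and 2-fold.

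From E16.5 to E18.5 (n = 3 each), where age and Get1 genotype differ together, skeletal muscle genes rose in bladder in 18 of 25, 19 adjusted over the list alone, (adjusted p = 6.53e-13, adjusted p = 0.0729 with an estimated correlation). The neuropeptide Npy rose from 5.04 ± 0.43 to 8.6 ± 0.27, and Tnnt3 from 7 ± 0.4 to 10.33 ± 0.18. The flavin monooxygenase Fmo5 (3.31), the lectin Itln1 (3.2), the protease Mmp10 (3.15), the noradrenaline carrier Slc6a2 (3.15) and Abca8a (3.06) rose. Hbb-y fell from 10.1 ± 0.47 to 5.64 ± 0.91, with Csn1s2a (-2.79) and Agbl4 (-2.7). Urothelium rose in 8 of 16 (adjusted p = 3.2e-07, adjusted p = 0.0729 with an estimated correlation), with Krt20 (3.03), Fabp4 (2.66) and Upk3a (9.9 ± 0.12 against 7.8 ± 0.16). Neurons and Schwann cells rose in 9 of 17, 10 adjusted over the list alone, (adjusted p = 8.55e-07, adjusted p = 0.167 with an estimated correlation). Simple epithelial keratins rose in 5 of 6 (adjusted p = 0.000432, adjusted p = 0.164 with an estimated correlation) and immune cells in 5 of 26, 6 adjusted over the list alone, (adjusted p = 1.68e-06, adjusted p = 0.1 with an estimated correlation). Epithelial junctions rose in 4 of 27, 6 adjusted over the list alone, (adjusted p = 1.56e-05, adjusted p = 0.1 with an estimated correlation), the gap junction gene Gjb2 by 2.77. The cell cycle list shifted down with 0 of 41 called (adjusted p = 4.44e-18, adjusted p = 0.0729 with an estimated correlation). The comparison called 1117 genes, 726 higher and 391 lower at E18.5, and 92.1% of second probe sets moved with the called gene.

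Against E14.5 (n = 2), E18.5 bladder (n = 3) had Tnnt3 51-fold higher (10.33 ± 0.18 against 4.65 ± 0.43), Synm up by 4.49, Acta1 by 3.83, and the dermatopontin gene Dpt by 4.03. The attractant chemerin, Rarres2, rose by 3.73, and Upk3a was at 9.9 ± 0.12 against 6.22 ± 0.28 (adjusted p = 3.82e-10). Hbb-y fell by 5.7 and Orly by 4. Skeletal muscle rose in 22 of 25 (adjusted p = 2.8e-15, adjusted p = 0.0563 with an estimated correlation). Urothelium rose in 11 of 16, 13 adjusted over the list alone, (adjusted p = 1.13e-08, adjusted p = 0.0563 with an estimated correlation), with Snx31 (3.63) and Psca (3.24). Smooth muscle rose in 10 of 15 (adjusted p = 4.96e-06, adjusted p = 0.178 with an estimated correlation), with Des (2.96) and Cnn1 (2.18). Immune cells rose in 11 of 26, 13 adjusted over the list alone, (adjusted p = 3.56e-07, adjusted p = 0.0871 with an estimated correlation). Interferon and antigen presentation rose in 11 of 25, 13 adjusted over the list alone, (adjusted p = 2.32e-05, adjusted p = 0.305 with an estimated correlation), the antiviral Rsad2 by 2.28. Cell cycle genes fell in 4 of 41 (adjusted p = 2.8e-15, adjusted p = 0.0611 with an estimated correlation), including Cdk1 (-1.13). Ehf was higher by 0.68 (adjusted p = 0.226) and Grhl3 by 0.95 (adjusted p = 0.547), neither called. The comparison called 1907 genes, 1265 higher and 642 lower.

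The change from E14.5 to E16.5 was then tested for a difference between skin and bladder. Serpina12 moved by 9.17 in skin and -0.28 in bladder, a difference of 9.45 ± 0.34 (SE, adjusted p = 2.05e-14). Dsc1 (8.09), Klk7 (7.61), Lce1m (7.42), Lce1b (7.07), the histidase gene Hal (7.08), Nol6 (7.96) and Hoxa7 (7.31) also moved further up in skin. Ttr moved by -5.97 in skin and 1.28 in bladder, and Map3k12 (-7.01), Thoc1 (-6.88), Afp (-5.89) and Krt4 (-5.85) moved further down in skin. At E14.5 Ttr was at 12.78 and 12.77 in skin replicates 1 and 2 and at 4.75 in replicate 3, and Afp at 13.39, 13.24 and 6.5, so these 2 changes rest on replicates 1 and 2. Krt12 moved further up in skin (5.3), and Ehf did not differ detectably (adjusted p = 0.709). Cornified envelope genes moved further up in skin in 23 of 45 (adjusted p = 4.07e-06, adjusted p = 0.932 with an estimated correlation). Skeletal muscle did so in 14 of 25 with 1 further down (adjusted p = 0.000241, adjusted p = 0.932 with an estimated correlation), and vascular endothelium in 10 of 16 with 4 further down (adjusted p = 0.0208, adjusted p = 0.932 with an estimated correlation). In all 7670 genes differed, 3077 further up and 4593 further down in skin, or 2983 and 2915 with the mean of all probe sets. The skin change lay across the divide and the bladder change did not, and second probe sets moved with the called gene in only 61.1%.

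Stomach and esophagus at E18.5 (n = 3 each), neighbouring organs on the same side of the divide, differed most among the lists in skeletal muscle by adjusted p. Pga5, a pepsinogen, was higher in stomach (14.71 ± 0 against 4.23 ± 0.15, adjusted p = 6.05e-09), from near the floor to near the top of the scale. The stomach claudin Cldn18 was at 14.07 ± 0.1 against 4.47 ± 0.26. Also higher were the phospholipases Pla2g12b (9.34) and Pla2g1b (9.09), the potassium channel subunit Kcne2 (7.96), prochymosin, Cym (7.92), colipase, Clps (7.69), the mucin Muc5b (8.04), Bpifb1 (8.52) and the cornified envelope gene Lce3f (12.74 ± 0.41 against 4.75 ± 0.87). Higher in esophagus were the cilium genes Efcab10 (4.53 ± 0.18 against 10.87 ± 1.09), Ccdc153 (-5.6) and Dynlrb2 (-4.85). So were the embryonic muscle myosin Myh3 (5.16 ± 0.85 against 9.79 ± 0.24), Csrp3 (-4.58) and Pax9, a factor of foregut and oral epithelium (7.82 ± 0.12 against 11.75 ± 0.37). Ehf did not differ detectably (-0.53, adjusted p = 0.35).

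Gastric epithelium genes were higher in stomach in 16 of 20 (adjusted p = 8.06e-20, adjusted p = 0.101 with an estimated correlation), such as the trefoil gene Tff1 (7.06) and Ctse (6.8). Cornified envelope genes were higher in 32 of 45 (adjusted p = 6.02e-19, adjusted p = 0.274 with an estimated correlation), such as Hrnr (6.96). Epidermal barrier lipid genes were higher in 9 of 18, 10 adjusted over the list alone, (adjusted p = 5.54e-09, adjusted p = 0.197 with an estimated correlation), for example Degs2 (4.04) and Fa2h (3.79). Aldehyde and oxidative defence genes were higher in 6 of 23, 7 adjusted over the list alone, (adjusted p = 3.37e-05, adjusted p = 0.0259 with an estimated correlation), for example Gpx2 (3.61) and Nqo1 (3.54). Intestinal genes were higher in 6 of 28, 11 adjusted over the list alone, (adjusted p = 0.000146, adjusted p = 0.66 with an estimated correlation), including Hnf4a (5.79). Skeletal muscle genes were lower in stomach in 19 of 25 (adjusted p = 1.26e-24, adjusted p = 0.014 with an estimated correlation). Airway ciliated and secretory genes were lower in 7 of 21, 8 adjusted over the list alone, and higher in 3 (adjusted p = 0.000119, adjusted p = 0.129 with an estimated correlation), the higher ones being Bpifb1, Muc5b and the secretoglobin Scgb1a1. The comparison called 1283 genes, 773 higher and 510 lower in stomach, or 575 and 634 as deposited, and 94.2% of second probe sets moved with the called gene.

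At E18.5, 5 tissues were compared for genes higher in a tissue than in each of the other 4. Skin was enriched for 747 genes, led by Serpina12 (14.46 ± 0.22, smallest log2 margin 9.41), Adipoq (7.79) and Krt27 (7.15), with 22 of 45 cornified envelope, 19 of 25 skeletal muscle, 16 of 27 hair follicle and 10 of 25 matrix genes. Small intestine was enriched for 736 genes, led by the pancreatic elastase Cela2a (12.21 ± 1.75, margin 6.9), the brush-border cadherin Cdhr5 (13.06 ± 2.86, margin 6.85) and the guanylin receptor Gucy2c (6.63), with 22 of 28 intestinal genes. Without replicate 4 it was enriched for 1019, with margins of 7.66, 8.5 and 8.32. Bladder, heterozygous for Get1, was enriched for 297 genes, led by the posterior Hox genes Hoxd13 (10.11 ± 0.22, margin 5.59) and Hoxa10 (5.11) and including the uroplakins Upk1a (3.55) and Upk3a (3.49), with 4 of 16 urothelium and 4 of 15 smooth muscle genes. Esophagus was enriched for 234 genes, led by the cilium genes Ccdc153 (10.39 ± 0.83, margin 5.6) and Efcab10 (5.41) and including Pax9 (3.93), with 5 of 21 airway and 3 of 12 nonkeratinised epithelium genes. Stomach was enriched for 189 genes, led by Pla2g1b (7.06) and Cldn18 (6.63), with 11 of 20 gastric and 7 of 45 cornified envelope genes. Both margins were set by small intestine replicate 4 (13.53 and 13.27) and were 8.54 and 8.77 without it. Groups simulated as unchanged gave 0, so genes some tissues share went untested.

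Ehf was highest in esophagus (11.05 ± 0.47) and stomach (10.52 ± 0.22), followed by bladder (9.11 ± 0.36), small intestine (7.49 ± 0.95) and skin (4.81 ± 0.22). Skin and small intestine lay on the other side of the divide from the rest. Compared only with tissues on their own side, a setting added after the data were seen, 522 genes were enriched in bladder, 296 in esophagus, 431 in stomach, 1636 in skin and 1864 in small intestine. Small intestine replicate 4 held stomach-type transcripts, and without it 1974 and 2078 genes were enriched in skin and small intestine within their side.

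**Figure D5:**
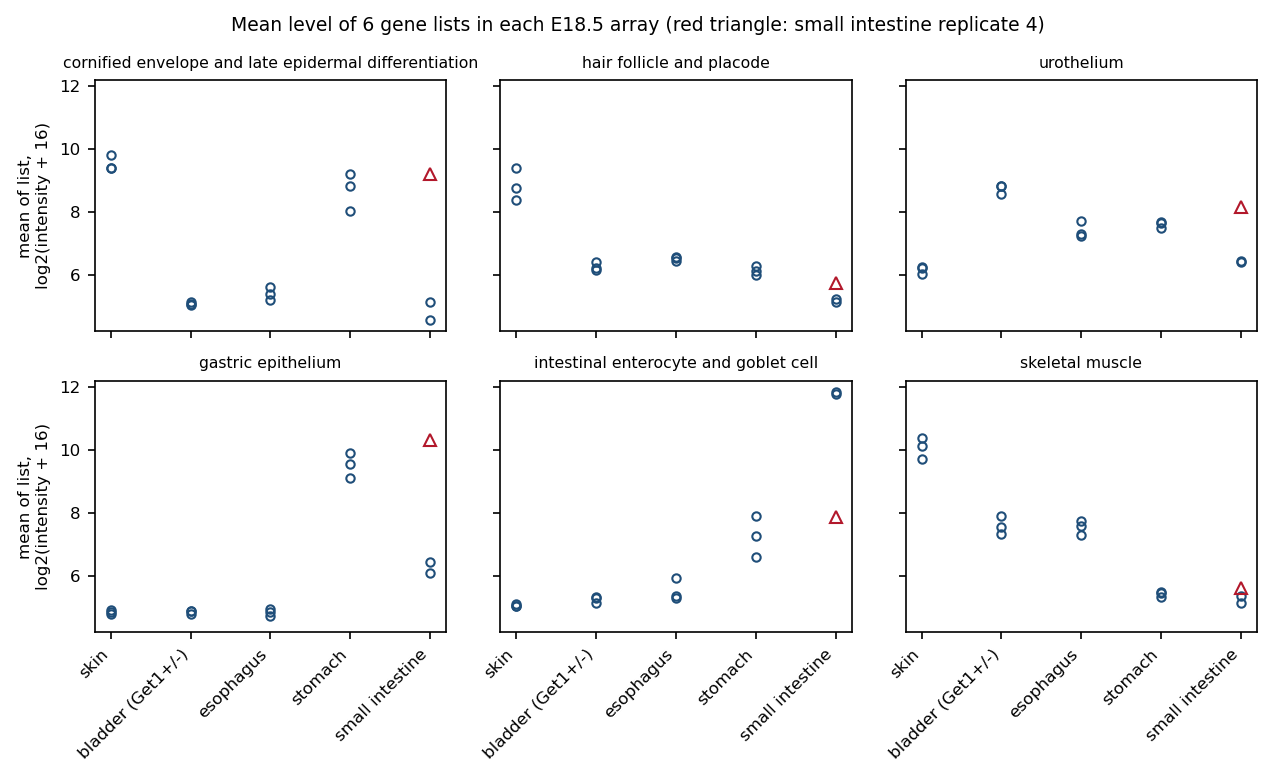
Mean log2 intensity of the members of 6 gene lists (y axis) on each E18.5 array of skin, bladder (Get1 heterozygous), esophagus, stomach and small intestine (x axis), each point an array. Small intestine replicate 4 (red triangle) has an intestinal list mean of 7.88, against 11.79 and 11.83 on the other small intestine arrays, and a gastric list mean of 10.32.

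Genes moving the same way in cornea (E17.5 against E14.5), skin and bladder (E18.5 against E14.5) were counted last, over the 16553 genes named in both tables, which were normalized separately. In all 3 tissues 64 genes rose, against 12.8 from the product of the tissues' shares, and 13 fell, against 1.04. The 13 became 6 without cornea E17.5 replicate 2, 8 without cornea E14.5 replicate 3, 21 without cornea E14.5 replicate 1, and 6 with only the groups compared in the fit. Fabp4, a fatty-acid carrier of fat cells and endothelium, rose by 2.73 in cornea, 4.17 in skin and 2.93 in bladder, the alcohol dehydrogenase Adh1 by 3.45, 2.35 and 3.21, and Klf5, a factor of basal epithelium, by 2.04, 3.78 and 1.94. Muscle genes were among them, with Acta1 (2.69, 4.09 and 3.83), desmin (2.44, 3.64 and 2.96), Tnni2, Mybpc1 and Tnnt3 among the 10 leading genes and 8 skeletal muscle list members in the set. In cornea, the Acta1 change ran from 2.11 to 3.78 and that of desmin from 1.81 to 3.65 with a left-out array, both highest without E17.5 replicate 2. The water channel Aqp1, Ndufa4l2 and Capn1 completed these 10. The 3 embryonic globins Hbb-y (-5.62, -7.25 and -5.7), Hba-x and Hbb-bh1 fell, with Kif15 (-1.63, -1.52 and -1.38), Sgo2a, Cep55, Ect2 and Cdc7, the chromatin genes Suv39h2 and Hells, and Lin9, Igf2bp1 and Atad5. Of fixed lists only the erythroid had falling genes. The cell cycle list had 0, which covers only its genes. The skin change used here lay across the divide. With E18.5 against E16.5 in skin and bladder, a setting added after the data were seen, 9 genes rose (product of shares 0.978) and 1 fell, Hbb-y (0.0511), and with E16.5 against E14.5, 6 rose and 0 fell, with 1 falling at an unadjusted p under 0.05 and 2-fold.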

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

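The tests of the lung label, of small intestine replicate 4 and of organ identity, and the comparison of skin with bladder from E16.5 to E18.5, were chosen only after the result was seen. The change with age differed between skin and bladder for 7670 genes from E14.5 to E16.5, with 3077 further up in skin and 4593 further down, and for 1747 genes from E16.5 to E18.5, with 818 and 929. From E16.5 to E18.5, with each organ on a side of the divide but E18.5 skin from an earlier study, Krt27 led the difference (8.89, adjusted p = 3.45e-10) and Krtap13 was furthest the other way (-7.18, adjusted p = 8.21e-10).

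The 3 arrays labelled lung carried thymus-type transcripts, with Rag1 at 14.22, Cd8a at 14.04, Themis at 13.67 and the thymic epithelial genes Prss16 at 13.22 and Ccl25 at 12.66. Lung tissue with some thymus carried along would raise alveolar genes. It stays open, since only the 4 that vary at least 2-fold over cornea ages were tested, a choice set by cornea. Of these 0 were called higher than in trachea. Probe sets that do not respond are argued against for 7 genes of the list, which vary over the other groups or were called higher, and stay open for the other 8. Another tissue under the lung label, such as thymus, is a candidate explanation, since 26 of 27 genes of a thymus list were called higher than in trachea, 3 of the 27 standing above the table median in trachea and 2 of the 30 genes listed standing in other lists. No biological explanation was tested, and comparisons with these arrays may not describe lung.

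Small intestine and the E16.5 and E18.5 skin arrays stood apart from the other arrays of their table. A difference in overall scale would vanish on quantile normalization, yet different tissues still correlated 0.213 better within a side than across. The organ identity test is circular, as the divide splits skin. E14.5 skin's lowest correlation with its side exceeded its highest with E16.5 skin by 0.121. A separate run that gives each probe set its own offset stays open and is consistent with the pairs of probe sets of a gene, whose ratios correlated better within a side by 0.432 at the median, though E16.5 with E18.5 skin reached only 0.265. Skin maturation between E14.5 and E16.5 is a biological difference in the design that remains untested beside it.

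Small intestine replicate 4 stood apart from replicates 1_3 and 3, with Cdx1 at 4 against 11 and 11.18 and the stomach genes Cblif at 11.29 and Gkn1 at 10.54. Probe sets shifted on their own in that array would not move in pairs, but the ratios of 2 probe sets of a gene correlated at 0.776. A mixture with a smaller part of stomach would lower intestinal genes little, but 27 of 28 were at least 2-fold lower, with a median change of -4.13. Stomach under an intestine label is a candidate explanation, since 16 of 20 gastric genes were at least 2-fold higher than in each other small intestine array, with Krt5 at 12.53 and Lor at 12.01 as in forestomach. No biological explanation was tested.

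Other splits of the same arrays were also counted. In 100 splits, no other split gave as many for the F test over cornea ages (4321 genes, highest other 1766). The same held for enrichment in bladder (297, 170), esophagus (234, 212) and small intestine (736, 164). For the rest other splits exceeded the real count, so chance was not excluded. Counting the real split, 4 reached it for genes higher in cornea than in both other tissues (1164, 1434). For lower ones 5 did (836, 1206). For enrichment 3 reached it in skin (747, 828) and 2 in stomach (189, 244). Of 40 relabellings, 17 gave as many list shifts (170, 222). The 3 against 3 comparisons have 10 splits, too few for a share under 0.05. Their real values and highest others were 2780 and 16 for cornea P28 against E14.5, 1507 and 27 for E15.5 against E14.5, 285 and 17 for P3 against E17.5, 284 and 1 for P7 against P3, 891 and 11 for P28 against P14, 3212 and 6 for trachea against the arrays labelled lung, 7856 and 0 for skin E16.5 against E14.5, 808 and 9 for E18.5 against E16.5, 7761 and 1 for E18.5 against E14.5, 1117 and 3 for bladder E18.5 against E16.5, and 1283 and 7 for stomach against esophagus. Cornea E17.5 against E15.5 gave 61 with a highest other of 138, and P14 against P7 gave 3 with 17. The cause of these higher counts in other splits was not tested.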

How the results depend on the processing

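The comparisons limited to a side of the divide, without small intestine replicate 4, from E16.5 to E18.5, against trachea only, without 2 cornea arrays together, and with both the block and an estimated correlation were added only after the result was seen. The deposited files hold no background signal, so what is dim could not be separated from what is absent, and the cause of the changes below was not tested except where stated. Counts of genes stayed within 1.5 times of the main count for all settings not listed here. Among named genes, the values as deposited ended 26 calls and a pseudocount of 1 ended 48, the mean of all probe sets ended 34 and reversed 2, and a left-out array ended 345 of the calls it could test, while 3854 stayed. The reversed ones were Ehf in skin E18.5 against E14.5 (0.07) and Lama3 in bladder E18.5 against E14.5 (-0.17). Of 170 list shifts, 15 stayed with an estimated correlation, 167 as deposited and 168 with a pseudocount of 1.

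As deposited, P14 against P7 called 1 gene. With a pseudocount of 1 it called 1, bladder E16.5 against E14.5 called 95 and enrichment in stomach 122, and without bladder among the tissues stomach enrichment gave 284. With the mean of all probe sets skin E18.5 against E16.5 called 507. With only the groups compared, which leaves fewer arrays to estimate the spread, cornea E17.5 against E15.5 called 0 (228 at an unadjusted p under 0.05 and 2-fold in limma), P3 against E17.5 called 136, P14 against P7 called 0 (66), bladder E16.5 against E14.5 called 0 (244), and 6 genes fell in cornea, skin and bladder.

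Without the fold limit, more genes are called by construction. In cornea these were 8564 for P28 against E14.5, 5271 for E15.5 against E14.5, 105 for E17.5 against E15.5, 1883 for P3 against E17.5, 1437 for P7 against P3, 5 for P14 against P7, 2731 for P28 against P14 and 10296 over 7 ages. Genes higher in cornea than in both other tissues numbered 3996 and lower ones 3070, and trachea against the arrays labelled lung gave 8547. Skin E18.5 gave 2308 against E16.5 and 11690 against E14.5, bladder E18.5 gave 2748 and 3996, and stomach against esophagus 2612. Enriched genes numbered 1666 in skin, 884 in bladder, 524 in esophagus, 317 in stomach and 1334 in small intestine, and 232 rose and 144 fell in cornea, skin and bladder.

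With the replicate number as a block and only the groups compared, cornea E15.5 against E14.5 called 986, E17.5 against E15.5 called 5, P3 against E17.5 called 152, P7 against P3 called 183 and P14 against P7 called 0 (84 at an unadjusted p under 0.05 and 2-fold in limma). Equal numbers were not shown to pair these arrays: correlations of equal numbers ran from -0.0559 to 0.00165, -0.114 to 0.247, -0.201 to 0.113, -0.2 to -0.147 and -0.106 to 0.243. For stomach against esophagus they ran from 0.0644 to 0.13, and all 3 arrays correlated best with their own number. For P28 against P14, where equal numbers correlated, the block changed no list call but the 2 given above.

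With P3 in place of E17.5, 1314 genes were lower in cornea than in both other tissues, and against trachea only 1906. Without the tissues across the divide, enrichment gave 522 genes in bladder, 431 in stomach, 1636 in skin and 1864 in small intestine, and without small intestine replicate 4 as well, 1974 in skin and 2078 in small intestine. Genes rising and falling in cornea, skin and bladder numbered 6 and 0 with E16.5 against E14.5 in skin and bladder, and 9 and 1 with E18.5 against E16.5. The difference in age effect between skin and bladder gave 1747 genes from E16.5 to E18.5.

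Leaving out an array gave ranges within 1.5 times except in 4 results. Cornea E17.5 against E15.5 ranged from 3 to 298, with 298, 3 and 5 without E15.5 replicates 1, 2 and 3, and 19, 170 and 22 without E17.5 replicates 1, 2 and 3, and 232 without E14.5 replicate 3 and E17.5 replicate 2 together. P14 against P7 ranged from 1 to 18, with 1 without P7 replicate 1 or P14 replicate 3 and 18 without P7 replicate 2 or P14 replicate 1. Bladder E16.5 against E14.5 ranged from 33 without E16.5 replicate 3 to 100 without E14.5 replicate 1, the lone E14.5 array then taken to vary like the other groups. Genes falling in cornea, skin and bladder ranged from 6 without cornea E17.5 replicate 2 to 21 without cornea E14.5 replicate 1, with 8 without cornea E14.5 replicate 3.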

Other observations

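The thyroid and liver-type marker lists used here were chosen only after the result was seen. Of 13 thyroid and parathyroid genes, 4 were called higher in trachea than in the arrays labelled lung and 9 were not. Tg was at 14.15, 14 and 13.51 on the 3 trachea arrays, against 7.38, 7.49 and 7.23 on the arrays labelled lung, and Iyd, which recycles iodide in thyroid, was at 12.22, 11.9 and 10.64. Pth, the parathyroid hormone, differed between trachea arrays, at 12.65, 11.58 and 7.87. Of 19 liver-type genes, 12 were called higher in trachea and 7 were not. Alb was at 12.97, 12.35 and 12.74 in trachea, against 7.1, 7.05 and 6.77 on the arrays labelled lung, but its fetal relative Afp was at 6.98, 6.84 and 7.63 against 6.86, 6.71 and 6.85.

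E14.5 skin replicates 1 and 2 held liver-type transcripts that replicate 3 did not. Alb was at 11.43, 11.31 and 4.67, Ttr at 12.78, 12.77 and 4.75, and the fibrinogen gene Fga at 10.93, 10.9 and 4.54. Small intestine replicate 4 also held such transcripts, with Alb at 12.06 against 4.69 and 9.24 in replicates 1_3 and 3.

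Lens transcripts varied between cornea arrays of an age. Cryaa, a lens crystallin, was at 9.44, 13.97 and 14 at E14.5, at 8.5, 12.52 and 8.86 at P14 and at 8.65, 11.01 and 9.07 at P28, while the 3 arrays at E15.5 lay at 8.29, 8.51 and 8.4. With E15.5 in place of E14.5, 2052 genes were called against P28.

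The surfactant genes Sftpc (4.07, 13.73 and 13.21) and Sftpb (4.32, 13.21 and 13.29) differed between E18.5 skin replicates 1, 2 and 3.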
